A study of Rattus norvegicus with 15 samples.

How the data were processed

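Total RNA of the left inguinal mammary gland was extracted with Trizol, and 80 ng per rat was amplified and biotinylated with the NuGEN Ovation V2 system and hybridised to an Affymetrix rat array, 1 array for each of the 15 rats. The authors deposited log2 expression values per probe set, made by RMA and quantile normalisation, and the values of the 2 deposited tables were equal on all 15 arrays (largest difference 0). The deposited table also gives a detection p-value from the MAS5 algorithm for each probe set and array, and the authors' detection call (present, marginal or absent) beside it. Per the submitters' processing notes the tools were GCOS, RMA, MAS5 and affy, and their versions and roles are not given in the sources used here. Nor are the genome build and the date of the probe set annotation, so no positions are given. The authors' own table of group means, log2 fold changes, p-values and adjusted p-values is of limma's form, per the file headers, but its fit is not described. At an adjusted p under 0.05 that table calls 300 probe sets for pregnancy minus control (150 higher, 150 lower), 5 for hormone minus control (1 higher, 4 lower), 0 for hormone minus pregnancy and 421 (159 higher, 262 lower) for the mean of both exposures minus control.

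Rats were grouped by the labels into control, pregnancy and hormone. The deposited table further holds 15 per-sample columns for 5 arrays of a group that matches none of the labelled samples, which were not used here, nor was that group's mean. MAS5 signals were not analysed here. Of 31099 probe sets, 57 control probe sets were left out and 31042 were tested, with no filter on intensity. An Entrez identifier in the deposited table linked 23371 of them to 14239 genes, while 7671 named no gene. Symbols were brought up to date by Entrez identifier against a rat gene table, which found 13762 genes, and were kept from the deposited table for 697 probe sets. The deposited table held 21 symbols in the form of dates, which were never used as names. Across the arrays 24052 probe sets had at least 1 present call, and the share present per array was 65.3 to 68.4%. Where a group had no present call, the ratio printed is the estimate from the measured values, and that group's level was not told from background. Such a ratio is no lower bound, since its sampling error goes both ways. Where neither group had a present call, no size of a gene's change is given. Hybridisation between close relatives was not resolved, which concerns Lilrb4, Lilrb2, Aagab with Aagab-ps2, and the RT1 genes.

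Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables. One linear model with a mean per group was fitted to all 15 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (residual df 12, prior df 2.70), two-sided tests for pregnancy minus control, hormone minus control and pregnancy minus hormone, and a moderated F test over the 3 groups. Benjamini-Hochberg adjusted p values under 0.05 over the 31042 probe sets of a comparison passed. Errors are the moderated standard errors of the difference.

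Named genes followed a rule: per comparison, 1 probe set per gene (the brightest that names a single gene), the 12 largest increases and 12 largest decreases among those that passed, and where fewer than 10 of a direction passed, all of them plus those with the smallest p up to 6, said not to have passed. Members of a list past the threshold were added, at most 4, or else the 2 with the smallest p, along with Igf1, Ghr, Areg, Esr1, Pgr, Tgfb3, Csn2, Wap, Lalba and Lbp. A few genes that the rule names are not reported here.

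For groups of genes, 33 lists of 701 symbols were written, of which 641 symbols were measured. They cover milk and secretory genes, luminal epithelium, basal myoepithelium, hormone-sensing cells, the growth hormone and IGF axis, the EGF family, TGF-beta, Wnt and Notch signalling, adipocytes, fatty acid synthesis, cholesterol synthesis, brown fat, oxidative phosphorylation, extracellular matrix, matrix proteases, B and plasma cells, T and NK cells, lymph node, antigen presentation, macrophages, mast cells, interferon response, acute phase and innate genes, proliferation, p53 and DNA damage, skeletal muscle, endothelium, blood, skin keratinocytes, Schwann cells and nerve, immediate early and stress genes, and the circadian clock. Each list was tested by limma's camera, two-sided, with a preset correlation of 0.01 on 1 probe set per gene, adjusted over the 33 lists. No list call held with a correlation estimated per list, where the smallest adjusted p was 0.449, 0.601 and 0.535 in the 3 comparisons. The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 3, 4 and 0 lists. List levels per array are means of the members' log2 values relative to the 15 arrays.

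The likeness of the pregnancy and hormone changes was measured by the correlation and covariance of the log2 differences across probe sets. Both share the controls, so 1000 simulated pairs of unchanged groups against the same controls gave the values that sharing produces, and every split of the controls into 2 and 3 gave values without sharing. The groups, the tests, the lists, the rule for names and the main set of alternatives were fixed before the data were examined. Alternatives were centred arrays, filters on intensity or on present calls on at least 5 arrays, 1 probe set per gene, another variance model, array weights, fits of 2 groups, an ordinary test, other thresholds (adjusted p under 0.1, a change of at least 1.5-fold), lymph node or muscle list covariates, a block by replicate number and each array left out. Fits with both covariates, fits without the 4 arrays over 0.5 log2 on the lymph node list or the 3 over 1 on the muscle list, list tests under covariates or block, and exact permutation tests of list levels (252 orderings, two-sided) were added after seeing the data.

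The procedure was tested on simulated data with 200 of 31042 probe sets changed: it recovered 68% of 50 at a log2 change of 0.5, 96% at 1, and 98% at 1.5 and at 2, with 11 false calls and 0 calls in the unchanged hormone comparison by limma. Of the 33 lists, camera called the 1 raised by 0.5 and 0 of the other 32. In other splits of the real arrays into groups of the same sizes, camera called a median of 11 lists for pregnancy versus control. The median was 9 for hormone versus control and 11 for pregnancy versus hormone. The median of called probe sets was 0 there, with up to 2795 for pregnancy versus control. The rates of recovery and of false calls therefore apply to the simulated data only.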

Results

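Gene expression was measured on Affymetrix arrays in the left inguinal mammary gland of 15 female Lewis rats, with 5 rats in each of 3 groups and 1 array per rat. Control rats carried sham capsules. Pregnancy rats went through a full-term pregnancy of 21 to 23 days, also with sham capsules, and their pups were taken away 4 to 6 hours after delivery, so that no suckling followed. Hormone rats carried 2 silastic capsules for 21 days, holding 100 µg of ethynyl estradiol, an estrogen, and 30 mg of megestrol acetate, a progestin. All rats then rested for about 49 days and were killed in metestrus. The arrays had between 65.3% (hormone replicate 5) and 68.4% (control replicate 5) of their probe sets called present, and their median log2 values lay between 7.71 and 7.77. The number of arrays, 5 per group, limits the precision of every value.

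Transcripts of tissues beside the gland differed widely between arrays of the same group. The lymph node list, genes of B and T cell zones and of lymph node stroma, stood 1.25, 1.34 and 1.32 log2 units above the mean of the 15 arrays in control replicates 1, 4 and 5, and 0.98 above it in pregnancy replicate 3. It was 0.73 below that mean (−0.73) in control replicate 2 and −0.63 in control replicate 6. The skeletal muscle list stood 1.53 and 1.92 above the mean in pregnancy replicates 7 and 9 and 3.46 above it in hormone replicate 4. Principal components of the 15 arrays were taken over the 15521 probe sets above the median mean level. The first held 40.6% of their variance. The same 4 lymphoid-rich arrays had its 4 highest scores, from 21.17 in pregnancy replicate 3 to 41.91 in control replicate 4.

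**Figure D1:**
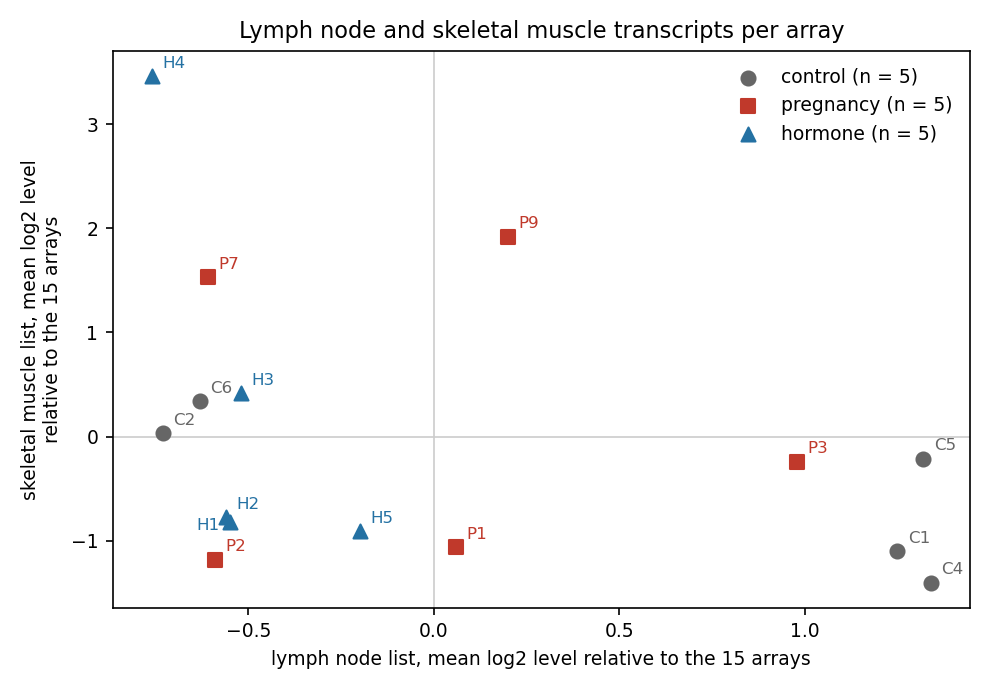
Each point is 1 array; the x axis gives the mean log2 level of the lymph node list and the y axis that of the skeletal muscle list, both relative to the mean of the 15 arrays. Control replicates 1, 4 and 5 and pregnancy replicate 3 lie at 0.98 or more on the lymph node axis, and hormone replicate 4 lies at 3.46 on the muscle axis.

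The first comparison asks whether a past pregnancy without suckling left a lasting change in the gland. After pregnancy, Gpnmb, Mmp12 and Wfdc3 were among the genes that rose, and Col6a3 was among those that fell. The lists of macrophage and of milk and secretory genes were higher by means of 0.30 and 1.02, both called by camera at the preset correlation. Both calls were lost with an estimated correlation (camera adjusted p = 0.449) and in the exact permutation test (adjusted p = 0.131). The fry test called both (adjusted p = 0.0303 and 0.0209). Gpnmb, a membrane glycoprotein of lysosome-rich macrophages, rose by 1.32 on the log2 scale (SE 0.15, n = 5 per group), or 2.49-fold, with an adjusted p of 0.00789, the smallest of all probe sets. Mmp12, the elastase of macrophages, rose 4.67-fold (log2 2.22, SE 0.35, n = 5 per group, adjusted p = 0.031). Wfdc3, a small whey acidic protein domain gene, was called present on 4 of 5 pregnancy arrays and on 0 of 5 control arrays. It was an estimated 8.13-fold higher (log2 3.02, 95% interval 1.97 to 4.08, SE 0.49, n = 5 per group, adjusted p = 0.0365). Col6a3, a chain of type VI collagen, fell by 0.51 (SE 0.09, n = 5 per group, adjusted p = 0.0489).

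Of 31042 probe sets, 61 passed, 36 higher and 25 lower, for 48 genes, while 9 of them named no gene. Their median absolute change was 0.593 on the log2 scale. After each array was centred on its median, 41 passed, 75.6% of them higher, against 59.0% in the uncentred values. The balance turned under array weights (43.2% of 1154 higher), with the lymph node list as a covariate (34.2% of 114) and without control replicate 2 (39.9% of 1430). It also turned with the lymph node and muscle lists both as covariates (41.4% of 29), a fit chosen after seeing the data. The other 9 of the 12 largest increases lay above all 5 controls in 5 of 5 pregnancy rats. Cd5l, secreted by macrophages, was 2.73 higher (SE 0.49), Car2, a carbonic anhydrase, 2.12 higher (SE 0.38), and the chemokine Ccl9 1.53 higher (SE 0.25). Lilrb4, an inhibitory receptor of myeloid cells whose relatives are close in sequence, was 1.58 higher (SE 0.23), and Mpeg1, the pore-forming perforin-2 of phagocytes, was 0.97 higher (SE 0.16). Lipa, the lysosomal acid lipase, and Tent5c, a poly(A) polymerase, rose by 0.74 (SE 0.14) and 0.97 (SE 0.18). Trem2, a lipid-sensing receptor of macrophages, and Cela1, an elastase, also passed as higher, but neither had a present call on any array of the 2 groups, so no size of change is given.

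Of the other genes that fell, some fell by more than Col6a3. Gria3, a glutamate receptor subunit, was lower by −1.20 (SE 0.17) in 4 of 5 pregnancy rats against all controls, with pregnancy replicate 3 at 6.53, above the lowest control, replicate 2, at 6.50. Emid1, a secreted protein with an EMI domain, changed by −0.88 (SE 0.14). Nipsnap1, a mitochondrial protein, changed by −0.42 (SE 0.06). Syt13, a synaptotagmin, passed as lower with no present call in either group, so no size of change is given. A further 7 genes fell, by between −0.42 and −0.36: Plag1, Mbd5, Gcnt2, Ttll3, Fbxl6, Adck5 and Gtf2i. All of these adjusted p values lay between 0.031 and 0.0498.

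**Figure D2:**
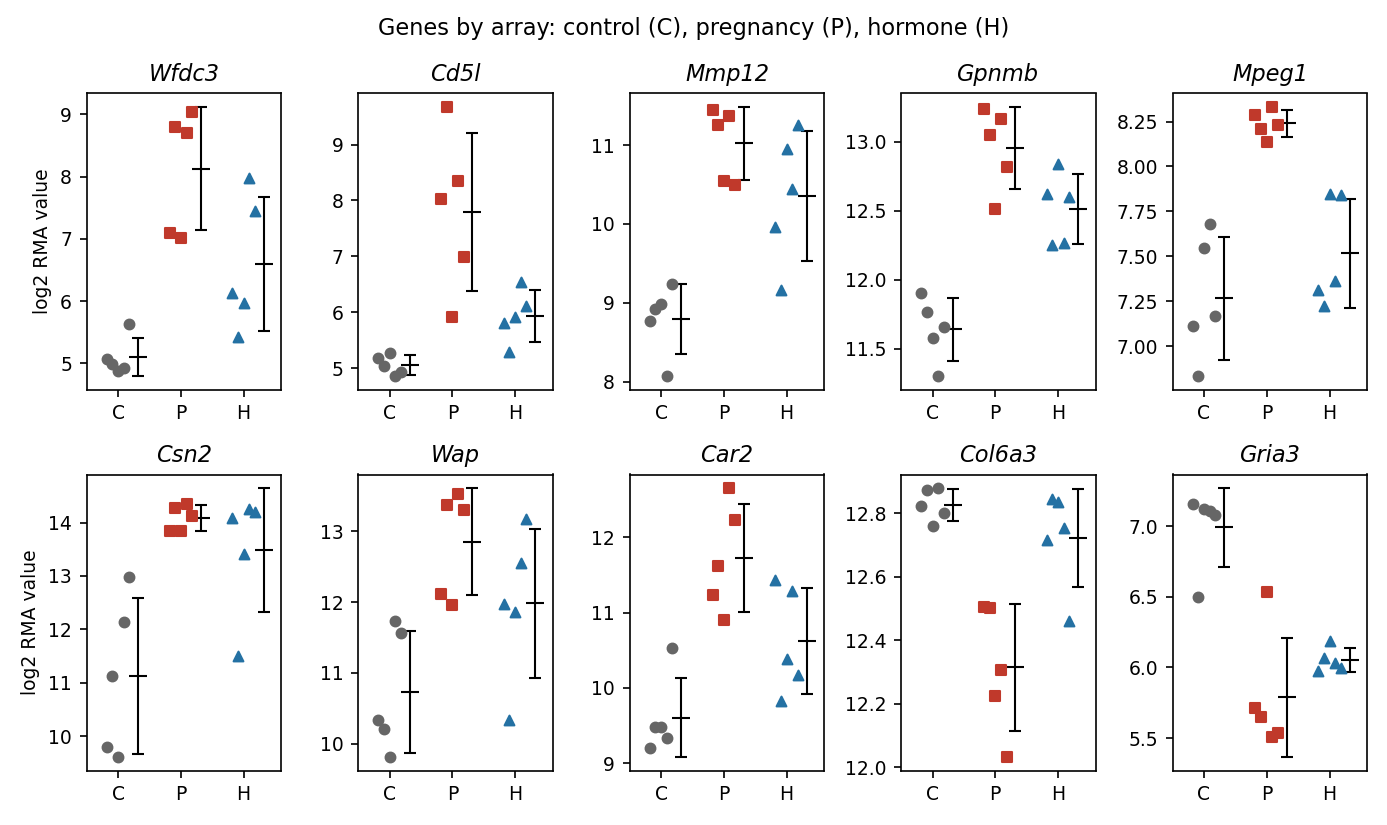
Log2 RMA value of 10 genes on each array (y axis) in the control (C), pregnancy (P) and hormone (H) groups, with the mean and SD of 5 arrays beside the points. Gpnmb, Mmp12 and Mpeg1 were above all controls in 5 of 5 pregnancy rats, while Csn2 and Wap, with mean differences of 2.96 and 2.12, varied most among controls and did not pass.

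Milk and secretory genes formed the highest list after pregnancy: all 18 measured members were higher, by a mean of 1.02 on the log2 scale (camera adjusted p = 8.12e-12; adjusted p = 0.449 with an estimated correlation). Xdh, xanthine dehydrogenase of the milk fat globule, rose by 0.37 (SE 0.06), Tf, transferrin, rose by 0.38 (SE 0.07), and 16 members did not pass over all probe sets. Adjusted over the list alone, 17 rose. The caseins and whey proteins had uneven differences. Csn2, beta-casein, was 2.96 higher (SE 0.62, adjusted p = 0.0697) and Wap, whey acidic protein, 2.12 higher (SE 0.51, adjusted p = 0.0724). Lalba, alpha-lactalbumin, was 0.36 higher (SE 0.11, adjusted p = 0.1). Its means, 14.02 in controls and 14.39 after pregnancy, lay near the highest values on the arrays, 14.45 to 14.57. Its smaller difference therefore cannot be told from a lack of room to rise. The list of luminal epithelium genes was 0.16 higher with an adjusted p of 0.117. Fatty acid synthesis genes, which also serve milk fat, were higher in 20 of 21 members by a mean of 0.46, beside an adipocyte list 0.40 higher. For the fatty acid list the camera adjusted p was 2.62e-07, or 0.449 with an estimated correlation. None of its members passed over all probe sets, and 14 rose and 1 fell adjusted over the list alone. Thrsp, a lipogenic regulator, was at 0.66 (SE 0.16) and Elovl5, a fatty acid elongase, at 0.70 (SE 0.19).

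Macrophage genes were higher in 22 of 23 members, by a mean of 0.30 (camera adjusted p = 9.4e-06; adjusted p = 0.449 with an estimated correlation), and Gpnmb and Itgam rose, while Trem2 passed without a present call. Itgam, the CD11b integrin, rose by 0.44 (SE 0.08, adjusted p = 0.0449), and adjusted over the list alone 7 members rose. Extracellular matrix genes were lower in 30 of 35 members, by a mean of −0.26 (camera adjusted p = 2.91e-07; adjusted p = 0.599 with an estimated correlation), of which Col6a3 fell over all probe sets and 16 fell adjusted over the list alone. The mast cell list was lower in 9 of 11 members, by a mean of −0.25 (camera adjusted p = 0.0322; adjusted p = 0.614 with an estimated correlation). Its protease genes Cpa3 and Cma1 were at −0.53 (SE 0.14) and −0.42 (SE 0.12), and 3 members fell adjusted over the list alone. That list's adjusted p was 0.064 and 0.0622 without control replicates 1 and 5, and 0.0539, 0.0809 and 0.0918 without pregnancy replicates 1, 2 and 7. The acute phase list was 0.32 higher (camera adjusted p = 0.00794, or adjusted p = 0.614 with an estimated correlation), and 1 member rose adjusted over the list alone. Orm1, a plasma glycoprotein without a present call in controls, was an estimated 1.42-fold higher, and complement C3 was at 0.87 (SE 0.27).

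Lists of fat cells and mitochondria were higher too, beside higher muscle transcripts in the same group. The adipocyte list was 0.40 higher (camera adjusted p = 0.000106; adjusted p = 0.671 with an estimated correlation), with the transcription factor Cebpa at 0.97 (SE 0.23) and the hormone leptin, Lep, at 1.06 (SE 0.30), and 2 members rose adjusted over the list alone. All 31 members of the oxidative phosphorylation list were higher, by a mean of 0.13 (camera adjusted p = 8.61e-06; adjusted p = 0.688 with an estimated correlation), with no member passing adjusted over the list alone. The skeletal muscle list was 0.66 higher (camera adjusted p = 0.0479; adjusted p = 0.818 with an estimated correlation), with replicates 7 and 9 at 1.53 and 1.92. Without each of these in turn the muscle list was 0.33 and 0.23 higher (adjusted p = 0.235 and 0.492), without pregnancy replicate 2 it was 1.01 higher, and without control replicate 4 it was 0.43 higher (adjusted p = 0.118). Its adjusted p was 0.103, 0.0608 and 0.0521 without control replicates 1 and 2 and hormone replicate 3. The cholesterol synthesis list was 0.19 higher (camera adjusted p = 0.029; adjusted p = 0.818 with an estimated correlation), with Sc5d, a sterol desaturase, at 0.31 (SE 0.08). Without pregnancy replicate 9 the cholesterol list was only 0.02 higher (adjusted p = 0.712), and its adjusted p was 0.0526 and 0.0649 without control replicates 4 and 6. Antigen presentation genes were 0.25 lower (−0.25; camera adjusted p = 0.0167; adjusted p = 0.818 with an estimated correlation), with RT1-Da at −0.36 (SE 0.16), beside a lymph node list at −0.50 (camera adjusted p = 0.0615). The antigen presentation list had an adjusted p of 0.064, 0.0661 and 0.152 without control replicates 1, 4 and 5, and 0.0919 and 0.0684 without pregnancy replicates 2 and 7.

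The count of 61 rested on single arrays. It was 7 without control replicate 1, 1430 without control 2, 3 without control 4, 506 without control 5, and 3 without pregnancy replicate 1, 7 or 9 in turn. It was 13, 37, 21, 5 and 34 without hormone replicates 1 to 5, which share the estimate of the spread. Of the 24 largest changes, Gpnmb alone passed in all 15 fits without 1 array (highest adjusted p 0.0408), while the others kept their direction in 15 of 15 and passed in 2 to 10. In fits chosen after seeing the data, 10 probe sets passed without the 4 lymphoid-rich arrays, 3 of them among the 61, and 0 passed by limma without the 3 muscle-rich arrays, where 2607 had an unadjusted p under 0.05, against 6799 in the full set. A moderated fit of these 2 groups alone called 8 probe sets. An ordinary unmoderated test, also of the 2 groups alone, called 1 probe set, which was not among the 61.

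The second comparison asks what a course of estrogen and progestin left behind. A small set of genes changed. A2m, alpha-2-macroglobulin, a plasma protease inhibitor, was called present on 5 of 5 control and 0 of 5 hormone arrays. It was an estimated 2.55-fold lower (log2 −1.35, 95% interval −1.71 to −1, SE 0.17, n = 5 per group, adjusted p = 0.0241). Dip2b, a disco-interacting protein homolog, fell by 0.93 (SE 0.13, n = 5 per group, adjusted p = 0.0316), and Nipsnap1 fell by 0.46 (SE 0.06, n = 5 per group, adjusted p = 0.0316). Cbln2, a secreted synapse organizer, rose by 0.74 (SE 0.11, n = 5 per group, adjusted p = 0.0379), and Clec4a1, a C-type lectin receptor of myeloid cells, rose by 0.55 (SE 0.08, n = 5 per group, adjusted p = 0.0316).

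**Figure D3:**
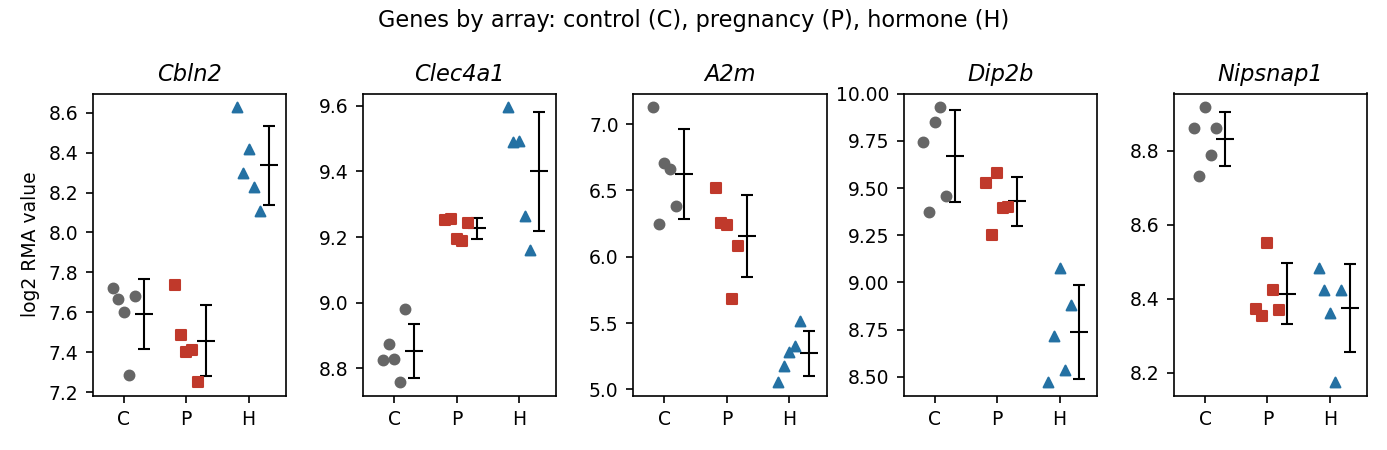
Log2 RMA value of 5 genes on each array (y axis) in the control (C), pregnancy (P) and hormone (H) groups, with the mean and SD of 5 arrays beside the points. Cbln2 was higher in the 5 hormone rats than in all 10 others, and Nipsnap1 was lower in all rats of both exposed groups than in the 5 controls.

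In all, 9 probe sets passed, 3 higher and 6 lower, for 7 genes, with 1 naming no gene. Genes next in line by p did not pass: Gpnmb was 0.87 higher (SE 0.15, adjusted p = 0.0755), and the myeloid receptor Lilrb2 0.61 higher (adjusted p = 0.0895). Lrrc51 and Trim36 (adjusted p = 0.0752 and 0.0802) had no present call in either group. Aagab-ps2, a pseudogene close in sequence to Aagab, was at −0.44 (adjusted p = 0.0615), Gria3 at −0.94 and the receptor Notch1 at −0.50 (adjusted p = 0.0895 each). Beta-casein, Csn2, was 2.36 higher (adjusted p = 0.139) and Wap 1.25 higher (adjusted p = 0.2), neither passing.

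Among lists, adipocyte genes were higher in 16 of 16 members after hormone, by a mean of 0.44 (camera adjusted p = 3.78e-05; adjusted p = 0.813 with an estimated correlation). Plin1, the lipid droplet coat perilipin, was at 0.51 (SE 0.17) and Pnpla2, a triglyceride lipase, at 0.41 (SE 0.14), and 8 members rose adjusted over the list alone. Macrophage genes were higher by a mean of 0.28 in 21 of 23 members (camera adjusted p = 0.000168; adjusted p = 0.601 with an estimated correlation), with 7 rising adjusted over the list alone. Milk and secretory genes were higher by a mean of 0.55 in 17 of 18 (camera adjusted p = 0.000451; adjusted p = 0.823 with an estimated correlation), with 6 rising adjusted over the list alone, among them Folr1, a folate receptor, at 1.03 (SE 0.23) and Xdh at 0.27 (SE 0.06). Oxidative phosphorylation genes were 0.11 higher (camera adjusted p = 0.000701; adjusted p = 0.823 with an estimated correlation), with the complex I subunits Ndufa5 at 0.25 (SE 0.10) and Ndufb5 at 0.24 (SE 0.11), beside a skeletal muscle list 0.75 higher (camera adjusted p = 0.0534). That muscle difference came from hormone replicate 4, at 3.46: without it the list was at −0.05 (adjusted p = 0.783). The Schwann cell and nerve list was 0.19 higher (camera adjusted p = 0.0162; adjusted p = 0.674 with an estimated correlation), with the myelin gene Prx at 0.29 (SE 0.10), and the blood list 0.22 higher (camera adjusted p = 0.0228; adjusted p = 0.601 with an estimated correlation), with the platelet gene Pf4 at 0.37 (SE 0.16). Without control replicate 5 the oxidative phosphorylation list was 0.07 and the blood list 0.14 higher, and the blood list had an adjusted p of 0.0555 without control replicate 6.

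The lists that were lower after hormone held mainly lymphoid genes, and 3 of the 5 control arrays were rich in lymph node transcripts. The lymph node list was at −1.03 (camera adjusted p = 0.000451; adjusted p = 0.813 with an estimated correlation), with the lymphoid chemokine Ccl21 at −0.87 (SE 0.20) and Fcer2, an immunoglobulin E receptor of B cells, at −2.18 (SE 0.83), and 1 member fell adjusted over the list alone. The B and plasma cell list was at −1.03 (camera adjusted p = 0.00672; adjusted p = 0.823 with an estimated correlation), though its immunoglobulin A heavy chain gene, Igha, was at 2.01 (SE 0.77). The T and NK cell list was at −0.89 (camera adjusted p = 0.000863; adjusted p = 0.823 with an estimated correlation), though the granule proteases Gzma and Gzmb were at 0.99 (SE 0.30) and 0.45 (SE 0.14). Antigen presentation genes were at −0.31 (camera adjusted p = 0.000451; adjusted p = 0.823 with an estimated correlation), with the immunoproteasome gene Psmb9 at −0.35 (SE 0.13). Proliferation genes were lower in 27 of 29 members, by a mean of −0.35 (camera adjusted p = 0.000451; adjusted p = 0.823 with an estimated correlation), with the replication gene Mcm3 at −1.09 (SE 0.31). The p53 and DNA damage list was at −0.15 (camera adjusted p = 0.0456; adjusted p = 0.601 with an estimated correlation). Its members went both ways, with Btg2, an antiproliferative gene, at −1.01 (SE 0.29) and Gadd45a, a stress gene, at 0.62 (SE 0.18), and 1 rose and 2 fell adjusted over the list alone. Its adjusted p was 0.0867, 0.107 and 0.0755 without control replicates 4 and 5 and hormone replicate 3. Without control replicates 1 and 4 the B and plasma cell list was at −0.64 and −0.68 (adjusted p = 0.089 and 0.0764). Without the 4 lymphoid-rich arrays, a fit chosen after seeing the data, the B and plasma cell, T and NK cell, lymph node and antigen presentation lists were at 0.94, 0.35, 0.16 and 0.02.

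The count of 9 rested on single arrays as well. It was 1 without control replicate 1, 1884 without control 2, 33 without control 6, and 0 by limma without control 4 or 5, where 4227 and 5017 probe sets had an unadjusted p under 0.05, against 6440 in the full set. It was 1 without pregnancy replicate 1 or 7, 0 without hormone replicate 1 or 4 (5307 and 5208 unadjusted), 1 without hormone replicate 2 or 3 and 2 without hormone replicate 5. All 5 named genes kept their direction in the 15 fits without 1 array, and A2m passed in 9 of them, Dip2b and Clec4a1 in 6, Nipsnap1 in 5 and Cbln2 in 4. Fits chosen after seeing the data called 0 probe sets by limma without the 4 lymphoid-rich arrays (2177 unadjusted) and 0 without the 3 muscle-rich arrays (4812 unadjusted).

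The third comparison asks whether the gland after pregnancy differed from the gland after hormone. Cbln2 was the only gene to pass: it was lower after pregnancy by −0.88 (SE 0.11, n = 5 per group, adjusted p = 0.0359), with each pregnancy rat below all hormone rats. Without 1 array it passed in 4 of 15 fits, with an adjusted p of up to 0.199. The 1 call became 0 by limma without any of control replicates 1, 2, 4 or 6, pregnancy replicates 3, 7 or 9, or hormone replicates 1 to 4, 2 without control replicate 5 or hormone replicate 5, and 9 without pregnancy replicate 2. Across the 15 fits 2046 to 3842 probe sets had an unadjusted p under 0.05, against 3092 in the full set. Cbln2 did not pass in fits chosen after seeing the data without the 4 lymphoid-rich arrays (adjusted p = 0.0605), where 4 other probe sets did, or without the 3 muscle-rich arrays, where limma called 0 (1117 unadjusted). Cbln2 was not among the 3 probe sets called by an ordinary unmoderated test of the 2 groups alone.

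Other genes with the smallest p values did not pass. Aagab, an adaptor protein partner, and A2m had no present call on the hormone arrays. They were an estimated 1.62-fold and 1.85-fold higher after pregnancy (adjusted p = 0.209 and 0.303). The pseudogene Aagab-ps2 was at 0.42 (adjusted p = 0.26), Dip2b at 0.69 and Ddx6, an RNA helicase, at 0.63 (adjusted p = 0.303 each). On the lower side were Tbx15 at −0.66, Dclk1 at −0.54, Apc2 at −0.50 and the collagen gene Col5a2 at −0.48 (adjusted p = 0.342 each).

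The matrix list had the smallest p between the exposures: 33 of 35 extracellular matrix genes were lower after pregnancy than after hormone, by a mean of −0.26 (camera adjusted p = 2.52e-11; adjusted p = 0.535 with an estimated correlation), and 13 fell adjusted over the list alone. All 18 milk and secretory genes were higher after pregnancy than after hormone, by a mean of 0.47 (camera adjusted p = 1.44e-06; adjusted p = 0.535 with an estimated correlation), with Mfge8, a milk fat globule protein, at 0.44 (SE 0.15) and Spp1, osteopontin, at 1.11 (SE 0.52). The fatty acid synthesis list was 0.27 higher (camera adjusted p = 8.1e-06; adjusted p = 0.535 with an estimated correlation), with the acetyl-CoA carboxylase Acacb at 0.79 (SE 0.24), and the cholesterol synthesis list 0.20 higher (camera adjusted p = 0.000456; adjusted p = 0.622 with an estimated correlation). The acute phase list was 0.26 higher (camera adjusted p = 0.00117; adjusted p = 0.535 with an estimated correlation), with A2m and the cytokine Il1b, at 0.42 (SE 0.17), having its smallest p values. The B and plasma cell list was 1.17 higher (camera adjusted p = 2.37e-05; adjusted p = 0.622 with an estimated correlation), with Jchain, which joins immunoglobulin A and M, at 1.51 (SE 0.86), beside a lymph node list 0.53 higher (camera adjusted p = 0.0425; adjusted p = 0.745 with an estimated correlation) and a T and NK cell list 0.50 higher (camera adjusted p = 0.00142; adjusted p = 0.71 with an estimated correlation). The proliferation list was 0.27 higher (camera adjusted p = 0.000115; adjusted p = 0.706 with an estimated correlation) and the luminal epithelium list 0.14 higher (camera adjusted p = 0.0216; adjusted p = 0.827 with an estimated correlation). The Schwann cell list was at −0.20 (camera adjusted p = 0.011; adjusted p = 0.535 with an estimated correlation), and the mast cell list at −0.14 (camera adjusted p = 0.0385; adjusted p = 0.622 with an estimated correlation), with Hdc, which makes histamine, at −0.43 (SE 0.13); 3 members fell adjusted over the list alone in each of these lists. Single arrays moved several of these means. Without pregnancy replicate 9 the cholesterol list was 0.04 higher (adjusted p = 0.206), the fatty acid list 0.17 and the acute phase list 0.17. Without pregnancy replicates 1, 2 and 7 the proliferation list was 0.41, 0.16 and 0.10 higher, and without hormone replicate 2 the milk list was 0.29 higher. Without pregnancy replicate 3 the lymph node list was 0.28 higher (adjusted p = 0.378), the T and NK cell list 0.23 higher (adjusted p = 0.163) and the luminal list 0.24 higher. The luminal list was 0.08 higher without pregnancy replicate 7 (adjusted p = 0.161), 0.04 higher without hormone replicate 1 or 2 (adjusted p = 0.429 and 0.337) and 0.27 higher without hormone replicate 5, and its adjusted p was 0.0549 and 0.0528 without pregnancy replicates 1 and 2. The mast cell list was at −0.07 without pregnancy replicate 7 (adjusted p = 0.17), and its adjusted p was 0.0561 without control replicate 5, 0.0549 and 0.154 without pregnancy replicates 1 and 2, and 0.054 without hormone replicate 2. The lymph node list also had an adjusted p of 0.0507 without control replicate 5, 0.0515 and 0.0952 without pregnancy replicates 1 and 9 and 0.132 without hormone replicate 4, and the Schwann cell list 0.0528 without pregnancy replicate 2.

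**Figure D4:**
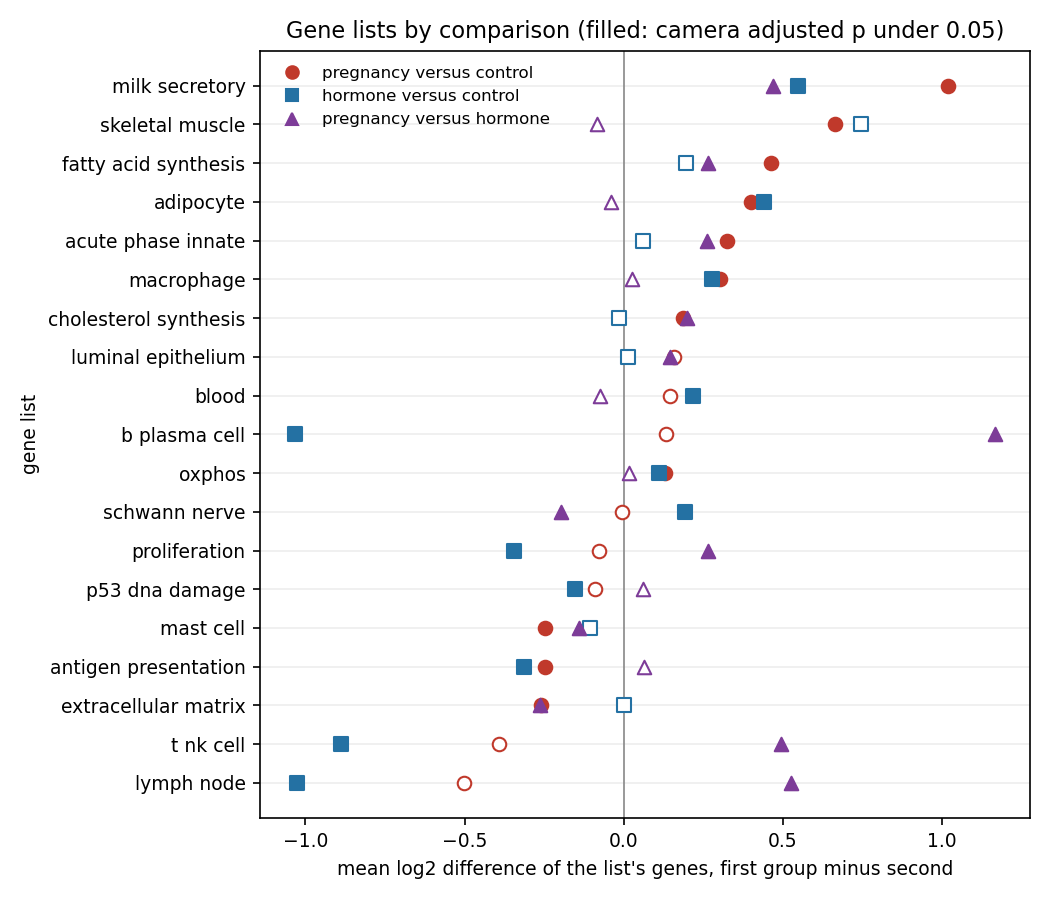
Mean log2 difference of each gene list (x axis, first group minus second) for the 19 lists called in at least 1 comparison (y axis), with filled symbols for a camera adjusted p under 0.05. Milk and secretory genes were at 1.02 after pregnancy and 0.55 after hormone, while extracellular matrix genes were at −0.26 in both comparisons that involve pregnancy.

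Pregnancy and hormone changes were also set against each other across genes, which are not independent replicates. The log2 differences of the 31042 probe sets correlated with r = 0.72 across genes, and 76.4% had the same sign. Both comparisons use the same 5 controls. Simulated groups without any change, sharing 1 control group drawn from the deviations of all 15 arrays, gave a mean r of 0.482. A share of 0.156 of the simulations lay at or above the measured r. By the SD of the lymph node list, the real controls varied more (1.09) than the pregnancy (0.66) and hormone (0.20) rats. The simulations may therefore understate the r and the covariance that sharing the real controls gives. The covariance, 0.0424, was above the simulated mean of 0.0132, with a share of 0.012 as large. That share was 0.0979, 0.116 and 0.0589 without control replicates 1, 4 and 5, and 0.0809 without the muscle-rich arrays. Without the lymphoid-rich arrays it was 0.197, but only control replicates 2 and 6 remained there. The deviations of 2 arrays from their mean mirror each other, so that simulation cannot decide the question. With different controls for each exposure, r averaged 0.392 over 20 splits and was above 0 in 19. Nipsnap1 and a probe set with no gene fell after both exposures, and 0 rises were shared by limma. At an adjusted p under 0.1, 15 falls and 5 rises were shared. In 100 simulations of unchanged groups, again sharing 1 control group drawn from all 15 arrays, the most shared falls were 0 at the first threshold and 1 at the second. The most shared rises were 0 at both. Unchanged groups are rarely called after adjustment, so counts near 0 follow from that setting. They do not show how many shared calls the 5 real controls alone would give. Further genes fixed in advance to be named passed in none of the 3 comparisons. Their values follow for pregnancy versus control, hormone versus control and pregnancy versus hormone. Esr1 was at 0.47, 0.58 and −0.10, Pgr at 0.07, −0.06 and 0.13, and Areg at −0.19, −0.22 and 0.03. Igf1 was at −0.16, 0.23 and −0.38, Ghr at 0.32, 0.59 and −0.27, and Tgfb3 at 0.44, 0.19 and 0.24. Lbp, of the acute phase list, was at 0.45, 0.08 and 0.38.

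An F test over the 3 groups called 10 probe sets. It called 4 without control replicate 1, 899 without control 2, 6 without control 5, 4 and 5 without pregnancy replicates 1 and 7, 21 and 18 without pregnancy replicates 2 and 3, and 5, 5, 3 and 5 without hormone replicates 1 to 4. It called 0 by limma without control replicate 4 or pregnancy replicate 9, where 4683 and 5239 probe sets had an unadjusted p under 0.05, against 6778 in the full set.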

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

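The tests of list levels per array, of differences between lists, of the spread among macrophage members and of the milk list with covariates were chosen after the results were seen; the counts of other splits of the arrays were planned.

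Whether chance can be excluded was asked by splitting the arrays in 100 ways of the same sizes, the real one included. Chance was not excluded for the 61 probe sets of pregnancy versus control, since 5 of 100 splits called as many and the highest other split called 2795. That split had the largest difference in lymph node transcripts, 1.52, and it was 1 of 4 splits with more than 5 times the real count, which points to a structure of the samples. Fewer splits than the planned limit of 5 of 100 called as many for the 9 probe sets of hormone versus control (3 of 100, highest other 106). The same held for the 1 of pregnancy versus hormone (3 of 100, highest other 16) and the 10 of the F test (3 of 100, highest other 1956). That does not exclude chance, since the split tests were several and not adjusted. Other splits here also called several times the real count, which points to a structure of the samples. By lymph node difference the highest such split ranked 9 for hormone versus control (1.11, against 1.03 in the real one) and 23 for pregnancy versus hormone (0.42, against 0.52), and it was not ranked for the F test. Nor was chance excluded for the 11 lists of pregnancy versus control (52 of 100, highest other 18), the 12 of hormone versus control (17 of 100, highest other 20) or the 12 of pregnancy versus hormone (39 of 100, highest other 20).

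Milk and secretory genes were higher after pregnancy by a mean of 1.02. A larger share of epithelium would raise luminal genes by a like amount where other cells lack them. The luminal list was only 0.16 higher, which argues against it as the whole source. The milk level minus the luminal level was 0.86 higher, in 5 of 5 pregnancy rats above all controls (exact permutation p = 0.00794, two-sided, the smallest 252 orderings can give). Both list differences had already been seen, so that test restates them and its p adds no further support. Lymph node and muscle RNA as the whole source is argued against by a mean of 0.84 with both lists as covariates (camera adjusted p = 5.93e-11), although that test uses the preset correlation and the exact test of the list itself had an adjusted p of 0.131. A lasting effect of pregnancy on secretory cells may remain, and a higher share of a secretory cell type within the epithelium was not tested.

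Macrophage genes were higher after pregnancy by a mean of 0.30. A lower share of lymphoid and epithelial RNA would raise other cell types alike. The macrophage level minus the matrix level was 0.56 higher, in 5 of 5 pregnancy rats above all controls (exact permutation p = 0.00794). The matrix list had already been seen to be lower, by −0.26, so that test only restates the 2 list differences and decides nothing further. What the values show is that the matrix list did not rise with the macrophage list, and that the luminal list was 0.16 higher, not lower. The members did not rise by equal amounts: their differences had an SD of 0.399, which none of the others among 126 splits reached (share 0.00794, highest other 0.361). That does not argue against more of the same cells, since members near background or shared with other cell types would rise less. More macrophages, a change in their state, and a pregnancy effect on the matrix list may each be involved and stay open.

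Lymphoid genes were lower after hormone, by −1.03 for the lymph node list. A piece of lymph node inside some samples, unrelated to treatment, could account for it: the list's level did not separate the groups (exact permutation p = 0.151), and 3 controls and 1 pregnancy rat had levels of 0.98 to 1.34. Lower levels of the list in every hormone rat than in every control are argued against by 2 control arrays at or under the highest hormone array. Of its 17 members 14 were lower and 3 higher. The member Ccl21, named for its small p, was lower in each hormone rat (12.70 or less) than in each control (12.94 or more). A p that misses the threshold does not exclude a hormone effect, which remains open.

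Single arrays stood far from the other 4 of their group in 10 of 153 groups for named genes and 9 of 99 for lists, where chance gives about 1 in 20 groups, that is 7.7 and 5.0. Control replicate 5 did so 5 times and control replicate 6 did so 4 times. In control replicate 6, Wfdc3 was at 5.64 against 4.88 to 5.08, Car2 at 10.52 against 9.20 to 9.49, Ttll3 at 6.83 against 6.97 to 7.01, and the acute phase list at 0.02 against −0.19 to −0.15. In control replicate 5, Lilrb4 was at 7.13 against 7.36 to 7.45, Ccl9 at 6.69 against 7.36 to 7.47, Cbln2 at 7.29 against 7.60 to 7.72, the blood list at −0.44 against −0.08 to 0.02 and the circadian list at −0.33 against 0.01 to 0.10. Gria3 was at 6.50 in control replicate 2 against 7.08 to 7.16 and at 6.53 in pregnancy replicate 3 against 5.51 to 5.71. In pregnancy replicate 2, Aagab-ps2 was at 9.81 against 10.04 to 10.12 and Aagab at 9.11 against 9.44 to 9.55. In pregnancy replicate 9 the cholesterol list was at 0.78 against −0.10 to 0.04 and the skin keratinocyte list at 1.09 against −0.22 to 0.05. In hormone replicate 1 the keratinocyte list was at −0.28 against −0.08 to −0.02 and the immediate early list at −0.33 against −0.04 to 0.07. The brown fat list was at 0.41 in hormone replicate 4 against −0.10 to −0.01, and the matrix list at 0.02 in hormone replicate 5 against 0.09 to 0.12.

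The effects of pregnancy and hormone differed, by the test of their difference, for Cbln2 (−0.88) and for 12 lists at the preset correlation: matrix (−0.26), milk and secretory (0.47), fatty acid synthesis (0.27), B and plasma cells (1.17), proliferation (0.27), cholesterol synthesis (0.20), acute phase (0.26), T and NK cells (0.50), Schwann cells (−0.20), luminal epithelium (0.14), mast cells (−0.14) and lymph node (0.53), none of them with an estimated correlation (adjusted p of 0.535 or more).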

How the results depend on the processing

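The fits with both covariates, those without the 4 lymphoid-rich or the 3 muscle-rich arrays, the exact permutation tests of list levels, and the list tests with covariates or block were chosen after seeing the data; the rest were planned. The MAS5 alternative was not run. There were 5 arrays per group, and the calls were few and depended on single arrays. Why they were few was not tested. A probe set with no present call was not told from its own background by the detection test, whatever its level. Directions held better than calls. Among 81 named gene results, 881 of 1215 comparisons without 1 array had the same direction and side of the threshold, 290 lost and 19 gained a pass, and 25 reversed; under other settings 796 of 1026 were the same, 201 lost and 13 gained a pass, and 16 reversed. Among 35 called list results, 482 of 525 without 1 array were the same and 43 lost the call; under other settings 233 of 385 were the same, 137 lost the call and 15 reversed. For the counts and the similarity, 69 of 120 without 1 array stayed within their bounds, and under other settings 51 did and 50 did not. Where a result moved, the cause was not tested, except that fits with fewer arrays have fewer samples and stricter or looser thresholds call fewer or more by construction.

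Counts of probe sets are given for pregnancy versus control, hormone versus control, pregnancy versus hormone and any difference among groups, against 61, 9, 1 and 10. Without 1 array they ranged from 3 to 1430, 0 to 1884, 0 to 9 and 0 to 899. Array weights gave 1154, 1374, 4 and 315, and an adjusted p under 0.1 gave 1330, 47, 2 and 121. Fits of 2 groups gave 8, 1 and 6. The ordinary unmoderated test, which for pairs of groups also left out the third group, gave 1, 0, 3 and 0 (5558, 4709, 4013 and 6374 unadjusted). None of its calls was among the main calls. The first count was 36 with an intensity trend and robust variance, and the second was 5 above the median level and 5 with 1 probe set per gene. A change of at least 1.5-fold left 31 and 5 of the first and second. The lymph node covariate gave 114 for the first and 0 for the third (3506 unadjusted), and the muscle covariate gave 3, 4 and, for the F test, 6. Both covariates gave 29, 0 (3021 unadjusted) and, for the F test, 0 (4994 unadjusted). Without the lymphoid-rich arrays they were 10, 0 (2177 unadjusted), 4 and 4, and without the muscle-rich arrays 0, 0, 0 and 0 by limma (2607, 4812, 1117 and 3066 unadjusted).

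The number in the sample title was taken as a replicate block only here. No pairing of rats by these numbers is stated. Group means were removed, and correlations were taken across the probe sets above the median mean level. Arrays sharing a number in different groups correlated at −0.317 to 0.415 (median 0.073, 9 pairs, 3 of them over 0.1). The 66 pairs of other numbers had a median of −0.01. As these ranged from −0.707 to 0.782, the 9 pairs cannot show whether rats sharing a number were linked. With the replicate block the counts were 0, 0, 0 and 0 by limma (3740, 7521, 3053 and 6213 unadjusted).

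Called lists numbered 11, 12 and 12, and 8 to 16, 10 to 14 and 10 to 14 without 1 array. An estimated correlation gave 0, 0 and 0 by camera (smallest unadjusted p 0.0229, 0.0222 and 0.0261), fry gave 3, 4 and 0 (smallest adjusted p 0.154 for the last), and the exact permutation test gave 0, 0 and 0 after adjustment, with 6, 5 and 2 lists under an unadjusted 0.05. The correlation across genes of the pregnancy and hormone changes was 0.392 with different controls for each exposure, against 0.72, and 0.641 to 0.81 without 1 array.

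The reversed genes were all far from passing. Without 1 array, Areg ranged from −0.431 to 0.118, −0.461 to 0.172 and −0.361 to 0.337 in the 3 comparisons, Pgr from −0.24 to 0.515, −0.371 to 0.172 and −0.165 to 0.576, Lbp in hormone versus control from −0.123 to 0.255 and Esr1 in pregnancy versus hormone from −0.248 to 0.037. In pregnancy versus control, Pgr was −0.067 with the lymph node covariate, −0.037 with the muscle covariate, −0.112 with both and −0.714 without the lymphoid-rich arrays, and with the block Areg was 0.416 and Ghr −0.059. In hormone versus control, Tgfb3 was −0.119 with the lymph node covariate, −0.141 with both covariates and −0.192 without the lymphoid-rich arrays, Lbp was −0.011 and −0.036 under the last pair, Areg was 0.271 with the block, and Pgr was 0.047 with array weights and 0.115 with the block. In pregnancy versus hormone, Areg was −0.086 with array weights and Pgr −0.003 without the lymphoid-rich arrays.

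Reversed lists were those of lymphoid genes, muscle and cholesterol synthesis. The arrays left out and the covariates were chosen on the lymph node and muscle lists, so a shift of those lists and of lists that move with them follows from the choice. In hormone versus control, B and plasma cells were at 0.535 with the lymph node covariate, 0.507 with both and 0.943 without the lymphoid-rich arrays, and T and NK cells at 0.113, 0.125 and 0.352. Without the lymphoid-rich arrays the lymph node list was at 0.164 there, and antigen presentation at 0.015 there and at 0.007 in pregnancy versus control. Skeletal muscle in pregnancy versus control was at −0.07 with the muscle covariate, −0.105 with both and −0.36 without the muscle-rich arrays. Cholesterol synthesis was at −0.069 in pregnancy versus control and −0.038 in pregnancy versus hormone with the block, and −0.022 in the latter without the muscle-rich arrays.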

Other observations

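The exact tests of list levels per array were chosen after seeing the data; the list tests were planned. In the B and plasma cell list, 6 of 15 members were higher and 9 lower after pregnancy. Igha, the immunoglobulin A heavy chain, was 3.23 higher on the log2 scale (SE 0.77, n = 5 per group), above all controls in 5 of 5 pregnancy rats, without passing over all probe sets (limma adjusted p = 0.0714), and it was the 1 member to rise adjusted over the list alone. Tnfrsf17, a plasma cell receptor, was 0.40 higher (SE 0.13, limma adjusted p = 0.114), and Jchain and IgG-2a, named after their values were seen, were 1.61 (SE 0.86) and 1.96 (SE 1.12) higher, none of them passing. Whether Igha differed from the other members was not tested. The list had a mean of 0.13 and a median of −0.39, with an adjusted p of 0.823. The matrix protease list was called in no comparison: it was at 0.30 after pregnancy (adjusted p = 0.0615) and 0.19 after hormone (adjusted p = 0.125), and at 0.11 with a median of −0.02 between them (adjusted p = 0.58). Mmp12 rose after pregnancy, and 2 members rose adjusted over the list alone. Mmp9, a gelatinase with no present call on the hormone arrays, was an estimated 3.63-fold higher after pregnancy than after hormone (limma adjusted p = 0.342). It was above all hormone rats in 5 of 5, and was the 1 member to rise adjusted over the list alone there.

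No member of the immediate early, Notch, TGF-beta, interferon or endothelium list passed over all probe sets in any comparison. The members named here passed only adjusted over their own list, with no adjustment across lists or comparisons. Their limma adjusted p over all probe sets lay between 0.0697 (Hspa1a after pregnancy) and 0.388 (Vwf, pregnancy versus hormone). Of all probe sets, 21.9%, 20.75% and 9.961% had an unadjusted limma p under 0.05 in the 3 comparisons, in the order below. In the immediate early and stress list, at −0.09, −0.13 and 0.04 for pregnancy versus control, hormone versus control and pregnancy versus hormone (adjusted p = 0.565, 0.236 and 0.46), the heat shock gene Hspa1a was at −0.73 (SE 0.16) after pregnancy and fell adjusted over the list alone. After hormone 3 members fell adjusted over the list alone, among them Myc, at −0.47 (SE 0.11), and Egr3, at −1.41 (SE 0.42). Egr3 was at 9.52, 9.46 and 9.58 in control replicates 1, 4 and 5, the lymphoid-rich controls, against 7.44 and 8.66 in the other controls. In the Notch list, at 0.04, 0.01 and 0.04 (adjusted p = 0.94, 0.851 and 0.568), 2 members rose and 3 fell after pregnancy adjusted over the list alone, with the target Nrarp at −0.32 (SE 0.08) and Notch3 at 0.68 (SE 0.19), while Notch1 fell after hormone adjusted over the list alone. In the TGF-beta list, at 0.09, 0.03 and 0.05 (adjusted p = 0.328, 0.921 and 0.194), the receptor Tgfbr3 was at 0.70 (SE 0.18) after pregnancy and rose adjusted over the list alone. In the interferon list, at −0.16, −0.09 and −0.07 (adjusted p = 0.0634, 0.324 and 0.361), Ifi44 was at −0.55 (SE 0.15) after pregnancy, and 1 member rose and 3 fell adjusted over the list alone. In the endothelium list, at −0.09, 0.06 and −0.14 (adjusted p = 0.565, 0.674 and 0.0715), the receptor Tek and the clotting factor Vwf were lower after pregnancy than after hormone, at −0.36 (SE 0.10) and −0.45 (SE 0.14), and fell adjusted over the list alone.

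The remaining lists were called in none of the 3 comparisons, in the same order. The Wnt list was at −0.11, −0.15 and 0.04 (adjusted p = 0.677, 0.739 and 0.841), hormone-sensing cells at −0.06, −0.13 and 0.07 (0.565, 0.851 and 0.201), the growth hormone and IGF axis at 0.01, 0.01 and 0.00 (0.565, 0.921 and 0.46) and the EGF family at 0.02, 0.04 and −0.01 (0.614, 0.845 and 0.841). Basal myoepithelium was at 0.10, −0.06 and 0.16 (adjusted p = 0.565, 0.707 and 0.0935), brown fat at 0.11, 0.11 and 0.00 (0.63, 0.921 and 0.46), skin keratinocytes at 0.14, −0.08 and 0.22 (0.56, 0.739 and 0.0809; the last was −0.02 without pregnancy replicate 9) and the circadian clock at 0.04, 0.06 and −0.02 (0.614, 0.756 and 0.961). Lists called elsewhere were not called for T and NK cells (−0.39, adjusted p = 0.469), proliferation (−0.08, adjusted p = 0.565), the p53 list (−0.09, adjusted p = 0.28), blood (0.14, adjusted p = 0.0687) and Schwann cells (−0.01, adjusted p = 0.69) after pregnancy. After hormone, fatty acid synthesis (0.20, adjusted p = 0.0534), cholesterol synthesis (−0.02, adjusted p = 0.862), matrix (0.00, adjusted p = 0.904), luminal epithelium (0.01, adjusted p = 0.921), acute phase (0.06, adjusted p = 0.739) and mast cells (−0.11, adjusted p = 0.707) were not called.

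The mean, the median and the direction of camera's test differed in sign for some lists, none of them called. After pregnancy these were hormone-sensing cells, B and plasma cells, p53 and Schwann cells. After hormone they were luminal epithelium, Notch, cholesterol synthesis, brown fat and matrix. Between pregnancy and hormone they were EGF, brown fat, matrix proteases, macrophages, p53, skeletal muscle and the circadian clock.

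Exact permutation tests of the list level per array, 5 against 5 and two-sided, called 0 lists after adjustment over the 33 lists, with 6, 5 and 2 lists under an unadjusted p of 0.05. After pregnancy the milk and macrophage lists were higher in 5 of 5 rats than in all controls, at the smallest p the design allows (exact p = 0.00794, adjusted p = 0.131), and the fatty acid list in 4 of 5 (exact p = 0.0159, adjusted p = 0.157). After hormone the mean level of the macrophage list was higher, and those of the Wnt and p53 lists lower, in 5 of 5 rats (exact p = 0.00794, adjusted p = 0.0873 each). In the Wnt list 12 of 25 members were higher and the median was −0.02. Its member Lef1, at −2.08 (SE 0.78), was at 10.91, 11.08 and 11.19 in control replicates 1, 4 and 5, the lymphoid-rich controls, against 7.58 and 7.43 in the other controls.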
